A study of Drosophila melanogaster and Drosophila simulans and Drosophila yakuba with 27 samples.

How the data were processed

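RNA was measured by sequencing in wandering third-instar larvae of 9 Drosophila lines reared at 25 °C. From each line, 1 library was made from eye-antennal discs, 1 from wing discs and 1 from brains, which gave 27 libraries of 3 tissues. The lines stand for 8 species: D. melanogaster, with the 2 strains RAL-208 and Canton S, D. simulans, D. yakuba, D. ananassae, D. pseudoobscura, D. willistoni, D. mojavensis and D. virilis. No line has a repeat library of a tissue, so the 9 lines serve as replicates of a tissue and the 3 tissues as replicates of a line.

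Per the labels, the authors extracted RNA with the RNAqueous micro kit, made Illumina TruSeq libraries, aligned reads with TopHat2 2.0 and counted them with HTSeq, whose version is not given in the sources used here. The genome builds are not given in the sources used here either, so no gene positions are reported. The authors deposited 27 tables of read counts per gene, each under the gene identifiers of its own species, and 1 table of normalised expression for all libraries under D. melanogaster gene symbols. The unit of that deposited table is a signal. For 9460 of 11435 genes in RAL-208 and 9673 of 11296 in Canton S, the values equalled scaled read counts within a tolerance of 1e-07. These totals are the genes with at least 2 values above 0. The counts were divided by 1 constant per gene and by 1 factor per library. Whether that constant follows the gene's exonic length was not tested. How the authors obtained the library factors and the orthologs is not given in the sources used here. Counts of D. melanogaster genes were paired with the table by value and by name. Of the 15439 table symbols, 11706 were current FlyBase symbols, 3294 were synonyms and 439 had no match. Where both routes could be compared, 8925 of 8929 genes agreed, and 334 named identifiers were not in the count tables. The table columns headed only by the name of D. melanogaster were assigned to RAL-208, because the other D. melanogaster columns name Canton S and because these values were proportional to the RAL-208 counts in those 9460 genes.

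The count tables hold no ortholog map, so comparisons across species used the deposited table, as laid down before the data were examined for that case. Of 15439 genes, 9832 had a value in every library, and the 7677 with a value of at least 1 in at least 9 libraries were tested. Tissues were compared with limma 3.58.1 in R 4.3.3 on log2(value + 1), with an intensity trend and with line as a block, fitted to all 27 libraries with 16 residual degrees of freedom. The block removes level differences between species, which also hold ortholog length and annotation. Deviations of libraries of the same line from their tissue means correlated at 0.625 to 0.863 across genes over 27 pairs, so the pairing by line was kept. The standard error of a log2 difference between tissues or lineages is limma's moderated standard error. Between the strains it was derived from the edgeR test below, as the absolute log2 difference over the square root of the F statistic. Lineage differences were tested as the interaction of tissue with the melanogaster subgroup (both D. melanogaster strains, D. simulans and D. yakuba; 4 lines against 5). Because these lines share ancestry, they are not independent draws. The strain comparison used edgeR 4.0.16 (TMM factors, quasi-likelihood F test) on read counts of the 6 D. melanogaster libraries, with tissue as a block, for 9476 genes with a CPM of at least 1 in at least 2 libraries, which leaves 2 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method, and a gene is called changed at an adjusted p under 0.05. The 6 comparisons of this kind answer separate questions and were each adjusted over their own genes.

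Before the data were examined, 22 gene lists were fixed from general knowledge: retinal determination, photoreceptor specification and furrow, antennal patterning, wing patterning, adult muscle precursors, neuronal function, neuroblasts, glia, posterior Hox, phototransduction, ecdysone response and stage, cell cycle, Notch signalling, EGFR signalling, cytoplasmic ribosomal proteins, muscle, fat body, salivary gland, hemocytes, ring gland, trachea and cuticle, and testis and germ line. They were tested with camera of limma at a preset correlation of 0.01, again with an estimated correlation, and with fry. The genes named in the text follow a rule from the same time. For each tissue comparison they are the 10 largest fold changes in each direction among called genes that had 1 sign in all 9 lines and a mean of at least 10 in both tissues together, plus the 4 called members of each list with the largest change. For the strain and lineage comparisons they are the 5 largest in each direction with a mean of at least 10, for divergence the 5 highest rates, for the Ornstein-Uhlenbeck fits the 5 lowest p with a mean of at least 10, and in D. simulans the gene white. A gene outside the rule is marked as chosen after its values were seen.

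Divergence was measured by phylogenetic independent contrasts of log2(value + 1) over the 8 species, with the D. melanogaster strains averaged, on a tree whose node ages were rounded from general knowledge: splits from D. melanogaster at 5, 13, 44, 55, 62 and 63 My, and 43 My between D. mojavensis and D. virilis. Tissues were compared by a two-sided exact permutation test that flips the signs of 7 contrasts. An Ornstein-Uhlenbeck model with 1 optimum was compared with Brownian motion per gene by a likelihood ratio over 80 values of the return rate alpha, from 0.001 to 30 per tree height, with p from 10000 Brownian simulations. The median rate of each list was compared, two-sided, with 10000 random lists of the same size and expression level. This comparison and the list tests between the strains were added after the data were seen. These steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

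The depth was 3642547 to 20473119 counted reads per library. On simulated data with 100 genes moved by 1 and 100 by 2 on the log2 scale, the tissue tests recovered 83% to 90% and 98% to 100% of them, the lineage tests 52% to 63% and 78% to 85%, and the strain test 43% and 82%, with 5 to 14 unchanged genes called. Of 5000 genes simulated under Brownian motion, 4.50% had a raw p under 0.05 and 0 were called, and the fits called 287, 1865 and 2096 of 5000 simulated with an alpha of 3, 10 and 30.

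The alternatives fixed before the data were examined were no block, no filter on low values, a pseudocount of 0.1, library medians set equal, each species once, the 18 libraries of a pair of tissues alone, leaving out each line or library, another lineage split, DESeq2 1.42.0 or other size factors for the strains, other branch lengths, each strain alone, median squares, and a Brownian null with tip noise. Those added after seeing the data were edgeR and DESeq2 on counts recovered for 5865 genes, limma on the same genes, genes with a mean of at least 10, the removal of doubtful gene entries, and the removal of lines whose libraries held transcripts typical of another tissue. Markers of another tissue were genes with a value of at least 10 in that tissue in all 9 lines and, in the median of the other 8 lines, at most 10% of that level in the library's own tissue. These criteria and the limits on the median share, 5% in wing discs and 10% in eye-antennal discs, were also set after seeing the data. Doubtful entries were genes below 0.5 in every library of 1 species and at least 5 in all others, and entries with the same values as another gene in all species but D. melanogaster. Genes missing in some species were left out of the comparisons, since a missing ortholog and no expression cannot be separated.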

Results

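Expression was measured by RNA sequencing in 3 tissues of wandering third-instar Drosophila larvae: the eye-antennal disc, which forms the eye, the antenna and the head capsule, the wing disc, which forms the wing and the notum, and the brain. Each tissue had 9 libraries, 1 from each of 9 lines of 8 species, so no tissue of a line had a repeat. The eye-antennal libraries held 3642547 to 12811084 counted reads, the wing disc libraries 4114414 to 14308891 and the brain libraries 4943047 to 20473119, with medians of 11529899, 10938286 and 9690840. The 10 genes with the most reads took 5.34% to 8.46% of a library. Values are the deposited signal, a read count scaled by gene and by library, given as mean ± SD over the 9 lines. Log2 differences between tissues and lineages are of the signal plus 1, with the standard error (SE) of the fit, and folds are taken from them. Between the strains, log2 differences are of read counts and the SE is derived from the F statistic.

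Expression profiles varied with both tissue and line. Of the total variation of 7677 genes over the 27 libraries, 52.9% lay between lines, 35.7% between tissues and 11.3% in neither. These shares are of the total sum of squares and were not scaled for there being more lines than tissues. Level differences between species also hold ortholog length and annotation. The shares therefore do not rank line above tissue as a source of biological variation. Brains lay apart from both discs on the first principal component, which held 32.7% of the variance, and both D. melanogaster strains lay apart from the other 7 species on the second, with 18.1%. Libraries of the eye-antennal and wing disc of the same line were closest, with a median Spearman correlation across genes of 0.942, against 0.854 for eye-antennal disc and brain and 0.801 for wing disc and brain. Libraries of the same tissue from different lines correlated at a median of 0.850. The most similar library belonged to the same line for 15 of the 27 libraries and to the same tissue for 12. These correlations are across genes, which are not independent replicates.

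**Figure D1:**
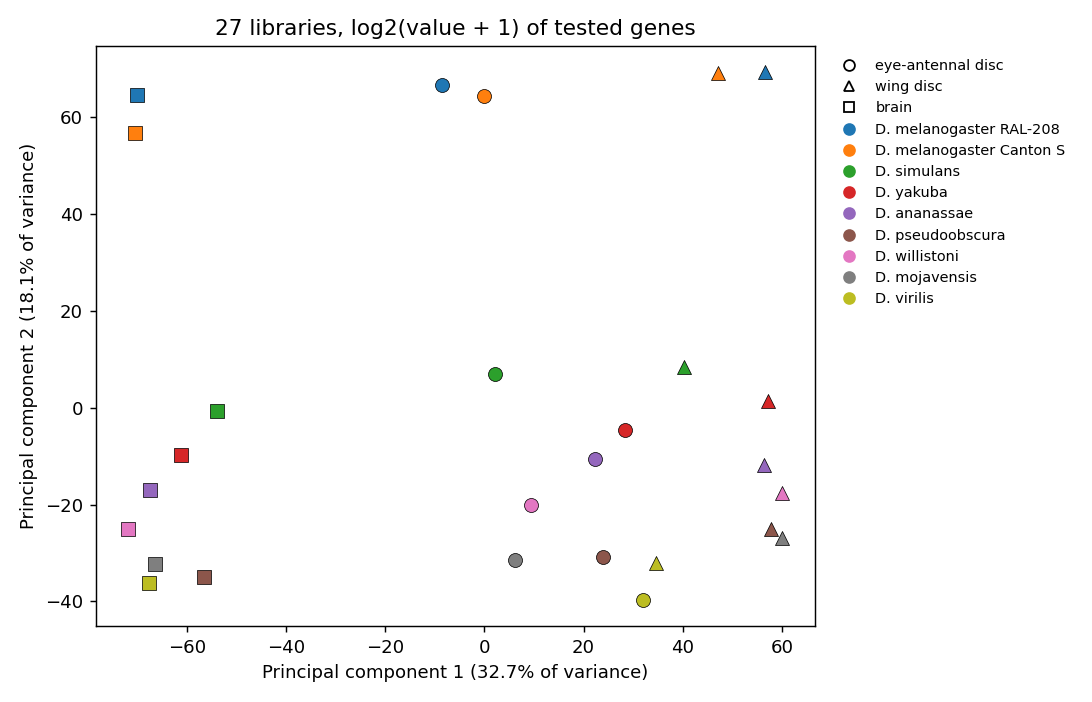
Scores of the 27 libraries on the first and second principal components of log2(signal + 1) of the tested genes, with 1 point per library, tissues as shapes and lines as colours. The first component holds 32.7% of the variance and parts the brains from the discs, and the second holds 18.1% and parts the D. melanogaster strains from the other species.

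The eye-antennal disc was compared with the wing disc to find the genes by which these discs differ in all lines. The Pax6 genes toy (FBgn0019650) and ey (FBgn0005558), which start eye development, were at 119 ± 34.7 and 58.3 ± 13.4 in the eye-antennal disc and at 4.63 ± 4.91 and 2.09 ± 1.89 in the wing disc (n = 9). The photoreceptor regulator gl (FBgn0004618) was 36.5-fold higher in the eye-antennal disc, a log2 difference of 5.19 with an SE of 0.40. The wing selector vg (FBgn0003975) was 21.6-fold higher in the wing disc, at 76.4 ± 22.2 against 3.07 ± 2.41, with a log2 difference of -4.44 and an SE of 0.17. The POU gene nub (FBgn0085424), needed for growth of the wing blade, fell by 4.13 on the log2 scale from wing disc to eye-antennal disc, with an SE of 0.21. Each of these differences had 1 sign in all 9 lines.

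Retinal determination genes were mostly higher in the eye-antennal disc: 6 of 11 were higher, 2 lower and 3 did not pass. After toy and ey, eya followed with a log2 difference of 3.22 (SE 0.19) and so with 2.49 (SE 0.15). Genes of photoreceptor specification and the morphogenetic furrow gave 18 higher, 3 lower and 2 not passed of 23, among them the Rhomboid protease gene ru at 4.34 (SE 0.27), lz at 4.12 (SE 0.27) and the proneural gene ato at 3.99 (SE 0.24). Antennal patterning genes gave 6 higher and 1 lower of 10, led by danr at 4.56 (SE 0.33), dan at 4.48 (SE 0.29), Lim1 at 2.08 (SE 0.16) and ct at 1.35 (SE 0.16). Camera called all 3 lists higher, and in all 9 lines none of these calls held with an estimated correlation: adjusted p = 0.135 with an estimated correlation for retinal determination, 0.0522 for photoreceptor genes and 0.0816 for antennal genes. In the 4 lines without brain transcripts in a disc above the limits, the photoreceptor list did pass with an estimated correlation (adjusted p = 0.0451). The retinal and antennal lists did not pass there (adjusted p = 0.205 and 0.165 by camera with an estimated correlation). Wing disc libraries also held transcripts typical of eye-antennal discs, at a median of 9.17% of their eye-antennal level in D. simulans, 8.37% in D. yakuba, 10.7% in D. ananassae and 6.70% in D. virilis, and at 1.37% to 3.68% in the other 5 lines. Without those 4 lines, the counts were 6 higher and 2 lower, 18 and 3, and 5 and 1 for these lists.

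Wing patterning genes were lower in the eye-antennal disc in 14 of 16 cases and higher in 0, with the POU gene pdm2 at -3.50 (SE 0.17) and the dorsal selector ap at -3.49 (SE 0.28) after vg and nub. This list kept its call with an estimated correlation (adjusted p = 0.00226). Adult muscle precursor genes were lower in 5 of 7 cases, among them Him at -1.89 (SE 0.28) and the mesodermal regulator twi at -1.82 (SE 0.18), with an adjusted p = 0.0816 with an estimated correlation. Cell cycle genes gave 14 lower and 2 higher of 20, with small changes such as -0.42 (SE 0.09) for the replication gene Mcm5, while the mitotic activator stg was higher by 0.72 (SE 0.13) and the cyclin-dependent kinase inhibitor dap by 0.69 (SE 0.11). The adjusted p was 0.176 with an estimated correlation, and the cell cycle counts were 8 lower and 2 higher without the 4 lines with eye transcripts. Without the 5 lines with brain transcripts in a disc they were 2 lower and 2 higher, while the median was -0.28 against -0.33 in all lines. Camera still called the list lower (adjusted p = 0.000362), but not with an estimated correlation (adjusted p = 0.330).

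Signalling genes were higher in part. Notch targets and components gave 7 higher and 1 lower of 13, with the E(spl) gene HLHmgamma at 3.27 (SE 0.15), m4 at 1.88 (SE 0.12) and HLHmdelta at 1.77 (SE 0.17). EGFR genes gave 7 higher and 2 lower of 15: the feedback inhibitor aos was at 1.69 (SE 0.10) and rho at 1.65 (SE 0.14), while the ligand gene vn was at -1.26 (SE 0.16). Their adjusted p values were 0.168 and 0.290 with an estimated correlation. Phototransduction genes gave 3 higher of 5, led by inaC at 3.39 (SE 0.30), with an adjusted p = 0.129 with an estimated correlation, and 1 higher without the 4 lines.

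Genes of the neuronal, glial, ring gland and muscle lists were also mostly higher in the eye-antennal disc. Neuronal genes gave 13 higher and 0 lower of 16, such as the synaptic vesicle gene Syt1 at 2.74 (SE 0.29) and elav at 1.52 (SE 0.19), and glial genes gave 7 higher and 0 lower of 11, led by the glial regulators repo at 2.83 (SE 0.17) and gcm at 2.02 (SE 0.19). Their adjusted p values were 0.178 and 0.0522 with an estimated correlation. Transcripts typical of the brain stood in the eye-antennal libraries at a median of 18.6% of their brain level in RAL-208, 12.0% in Canton S, 14.1% in D. simulans and 10.3% in D. mojavensis, and in the wing libraries at 6.32% in D. simulans and 5.12% in D. virilis. In the 4 lines without such transcripts above the limits, the neuronal count was 5 higher and 0 lower, with a median of 0.83 against 1.09 in all 9 lines. Camera still called the neuronal list (adjusted p = 9.24e-05), but not with an estimated correlation (adjusted p = 0.205). The glial count was 7 and 0, and the glial list then passed with an estimated correlation (adjusted p = 0.0417), as it did without the 4 lines with eye transcripts (adjusted p = 0.0247). The 7 ring gland genes were all higher, led by the adipokinetic hormone gene Akh at 4.66 (SE 0.47) and the ecdysone synthesis genes sad at 3.89 (SE 0.42) and phm at 3.76 (SE 0.42), with an adjusted p = 0.0816 with an estimated correlation. Akh stood at 91.1 in the D. willistoni wing library and at 0 to 4.79 in the other wing libraries. Muscle genes gave 8 higher of 12, such as Tm2 at 1.70 (SE 0.42), with an adjusted p = 0.400 with an estimated correlation, and 2 higher without the 4 lines with eye transcripts. Ring gland genes then gave 5 higher, and adult muscle precursors 3 lower. Without the 5 lines with brain transcripts in a disc, these counts were 6 higher for muscle, 4 higher for ring gland and 2 lower for adult muscle precursors. Their medians were then 2.04, 2.06 and -0.31, against 1.46, 2.06 and -0.42 in all 9 lines. Camera still called all 3 lists at the preset correlation. None of these 3 calls held with an estimated correlation (adjusted p = 0.310, 0.205 and 0.205 by camera).

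The other lists between these discs gave fewer or mixed calls. Of 66 ribosomal protein genes none passed in either direction, although camera called the list lower at a median of -0.09, with an adjusted p = 0.577 with an estimated correlation. Camera called none of the following lists. Neuroblast genes gave 7 higher and 3 lower of 14, with tll at 2.59 (SE 0.22) and nab at -2.05 (SE 0.28). Hemocyte genes gave 3 higher and 1 lower of 6, ecdysone response genes 2 and 1 of 17, and trachea and cuticle genes 1 and 2 of 7, among these vvl at -3.46 (SE 0.21) and trh at -2.14 (SE 0.15). Among the 3 posterior Hox genes, Ubx was lower by a log2 difference of -1.94 (SE 0.29). None of the 7 fat body, 2 salivary gland or 3 testis and germ line genes passed. For the trachea and posterior Hox lists the medians, 0.34 and 0.12, and the means, -0.55 and -0.49, differ in sign, and the test followed the mean. For the salivary gland and testis lists the medians, 0.24 and 0.01, stood against a test direction of lower.

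In all, limma called 1633 of 7677 genes, 1154 higher in the eye-antennal disc and 479 higher in the wing disc, and 631 and 60 of them by at least 2-fold. The remaining genes of the naming rule spanned log2 differences of 4.16 for the amyloid precursor-like gene Appl to 5.33 for CG9335 (FBgn0032895), with CG34377 at 4.70 and CG14516 at 4.45 between them, and of -2.07 for the cuticle gene Cpr49Ag, -2.17 for CG17278 and -2.52 for the Hox gene Antp to -3.56 for the homeobox gene Dr. Camera called 14 of 22 lists. Adjusted over the list alone, counts changed only for antennal patterning (7 higher), wing patterning (1 higher, 14 lower), neuronal (14 higher), neuroblast (8 higher), glial (8 higher), ecdysone (4 higher), cell cycle (15 lower), muscle (9 higher), hemocyte (4 higher) and trachea and cuticle genes (3 higher). Without the 4 lines with eye transcripts 1219 genes were called, 959 and 260, and without the 5 lines with brain transcripts in a disc 753, 615 and 138, of which 1095 and 708 were among the 1633. The balance of directions depended on scaling and test: medians set equal gave 1043 higher and 773 lower, and on 5865 genes with recovered counts limma gave 849 and 448, DESeq2 857 and 782 and edgeR 725 and 1008. Without the line block 709 genes were called, all of them among the 1633.

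**Figure D2:**
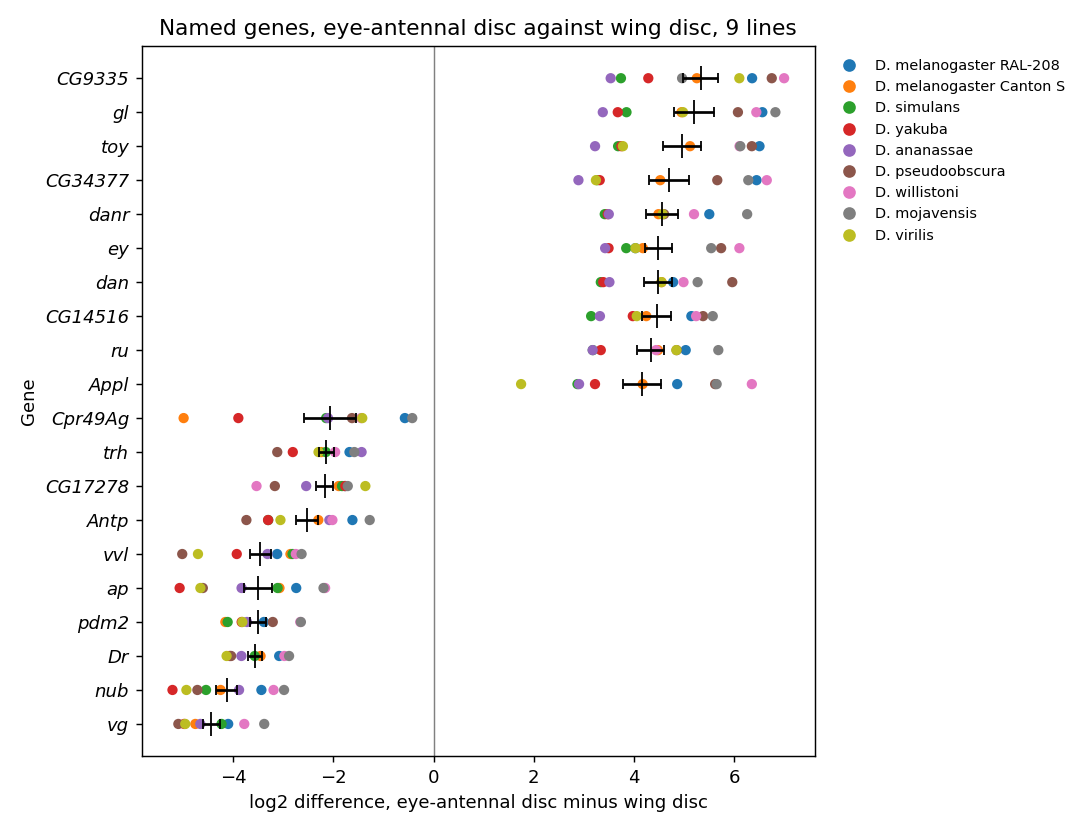
Log2 difference in signal plus 1, eye-antennal disc minus wing disc, for the 20 genes of the naming rule, with 1 point per line, black marks for the mean over 9 lines and bars for its SE. The points of each gene lie on 1 side of 0, and D. simulans, D. yakuba and D. ananassae have smaller differences for gl, toy and ey than the means of 5.19, 4.96 and 4.49.

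The eye-antennal disc was compared with the brain to set an epithelial disc with developing photoreceptors against the central nervous system. Of the 10 genes named as higher in the brain, 5 encode neuropeptides or insulin-like peptides: hug (FBgn0028374), which encodes hugin, was at 63.1 ± 27.1 in the brain and 1.54 ± 2.86 in the eye-antennal disc (n = 9), a log2 difference of -4.98 with an SE of 0.36. The insulin-like peptide genes Ilp3 and Ilp2 differed by -4.15 (SE 0.34) and -4.14 (SE 0.51), the myosuppressin gene Dms by -4.31 (SE 0.47) and capa by -4.24 (SE 0.41). In the other direction, gl was 8.45-fold higher in the eye-antennal disc, at 109 ± 35.6 against 12.3 ± 6.41, and the Pax gene eyg (FBgn0000625) 7.72-fold, at 22.1 ± 3.44 against 2.14 ± 1.23. The ecdysone-inducible gene ImpE2 was 6.73-fold higher there, at a log2 difference of 2.75 with an SE of 0.22.

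Retinal determination genes gave 8 higher, 0 lower and 3 not passed of 11, with toe at 2.81 (SE 0.15), eya at 2.39 (SE 0.19) and so at 2.32 (SE 0.15) after eyg. Photoreceptor genes gave 19 higher and 1 lower of 23, with lz at 2.87 (SE 0.27) and ro at 2.60 (SE 0.21). Notch genes gave 9 higher and 0 lower of 13, such as HLHmdelta at 2.34 (SE 0.17) and malpha at 2.02 (SE 0.07), and EGFR genes 11 higher and 2 lower of 15, such as the receptor gene Egfr at 1.75 (SE 0.12). The adjusted p was 0.233 with an estimated correlation for the retinal, photoreceptor and Notch lists and 0.281 for EGFR. Ribosomal protein genes were higher in 63 of 66 cases by small amounts, with a median of 0.45 and RpS20 at 0.61 (SE 0.09), and an adjusted p = 0.458 with an estimated correlation. Trachea and cuticle genes gave 5 higher and 2 lower of 7, among them the chitin deacetylase genes serp at 2.56 (SE 0.19) and verm at 2.54 (SE 0.15), with an adjusted p = 0.233 with an estimated correlation. Muscle genes gave 6 higher of 12, such as up at 1.61 (SE 0.45), with an adjusted p = 0.687 with an estimated correlation.

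Neuronal genes were lower in the eye-antennal disc in 15 of 16 cases and higher in 0, led by the vesicular glutamate transporter gene VGlut at -3.84 (SE 0.39) and the GABA synthesis gene Gad1 at -3.64 (SE 0.31). Neuroblast genes gave 10 lower and 1 higher of 14, with pros at -3.39 (SE 0.41), cas at -3.16 (SE 0.25) and wor at -2.88 (SE 0.26), and all 3 posterior Hox genes were lower, with abd-A at -2.35 (SE 0.25). Their adjusted p values were 0.233, 0.458 and 0.233 with an estimated correlation. The brain-typical transcripts in eye-antennal libraries, at 10.3% to 18.6% of their brain level in RAL-208, Canton S, D. simulans and D. mojavensis, and at 1.83% to 5.53% in the other 5 lines, were measured in the same libraries as these differences. Without those 4 lines, neuronal genes gave 14 lower and 0 higher, neuroblast genes 10 and 1 and posterior Hox genes 3 and 0.

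Camera called no other list in this comparison. Glial genes gave 6 lower and 4 higher of 11, with wrapper at -3.27 (SE 0.27) and Eaat1 at -3.26 (SE 0.35). Wing patterning genes gave 6 higher and 8 lower of 16, antennal genes 4 and 4 of 10, adult muscle precursors 2 and 3 of 7, phototransduction genes 1 and 1 of 5, ecdysone response genes 7 and 1 of 17, cell cycle genes 9 and 3 of 20, and hemocyte genes 1 and 1 of 6. Gp150 was the 1 of 2 tested members of the salivary gland list that was higher, at 1.92 (SE 0.10). Ptth, the prothoracicotropic hormone gene, was the 1 of 7 tested members of the ring gland list that was lower, at -1.87 (SE 0.21). Of the 7 fat body and 3 testis genes 0 passed. The ring gland list had a median of 0.14, a mean of -0.10 and a test direction of lower, and for wing patterning camera pointed lower and fry higher. The ecdysone median over the 15 genes with recovered counts was 0.06 and became -0.01 with DESeq2.

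Limma called 4039 of 7677 genes, 1978 higher in the eye-antennal disc and 2061 higher in the brain, 579 and 925 of them by at least 2-fold. The naming rule also gave CG13064 at 3.35 (SE 0.43), CG4914 at 2.99 (SE 0.20), CG9134 at 2.87 (SE 0.18), CG4374 at 2.86 (SE 0.13), CG12481 at 2.75 (SE 0.30) and CG9782 at 2.73 (SE 0.21), and, higher in the brain, CG12239, CG1552, CG14989, CG4409 and Drep-3, at log2 differences of -4.57 to -4.01. Camera called 10 of 22 lists. Adjusted over the list alone, counts changed for wing patterning (9 lower), glial (7 lower), ecdysone (6 higher), cell cycle (10 higher), EGFR (3 lower) and muscle genes (10 higher). Without the 4 lines with brain transcripts 3328 genes were called, 1619 and 1709, of which 3178 were among the 4039. Without the line block 2122 were called, all among the 4039. The balance of directions depended on scaling and test, and with medians set equal 2132 were higher and 1906 lower. On 5865 genes with recovered counts limma gave 1702 and 1556, DESeq2 1509 and 1889 and edgeR 1506 and 1738.

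The wing disc was compared with the brain in the same way. The odorant-binding protein gene Obp44a (FBgn0033268) had the largest difference of the genes named here, 101-fold higher in the brain than in the wing disc, where it stood at 205 ± 266 (n = 9), with a log2 difference of -6.66 with an SE of 0.43. The neuronal RNA-binding protein gene fne (FBgn0086675) was 74.5-fold and the neuronal transcription factor gene nerfin-1 (FBgn0028999) 60.5-fold higher in the brain. In the wing disc, vg was 12.8-fold and nub 12.4-fold higher, and the T-box genes Doc1 and Doc3 differed by 3.47 (SE 0.14) and 3.25 (SE 0.14). ImpE2 was 10.6-fold higher in the wing disc, against 397 ± 144 in the brain.

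Wing patterning genes were higher in the wing disc in 15 of 16 cases and lower in 1, with the Iroquois gene ara at 2.83 (SE 0.11) and kni at 2.78 (SE 0.13). Ribosomal protein genes were higher in 64 of 66 cases, with a median of 0.54 and RpLP0-like at 0.76 (SE 0.10), and cell cycle genes in 14 of 20 against 2 lower, with the mitotic gene fzy at 0.77 (SE 0.07). Trachea and cuticle genes gave 6 higher and 0 lower of 7, among them vvl at 2.37 (SE 0.21) and the chitin organisation gene knk at 2.36 (SE 0.10). The adjusted p values were 0.174, 0.575, 0.641 and 0.158 with an estimated correlation. Neuronal genes were lower in 15 of 16 cases, with the complexin gene cpx at -5.54 (SE 0.42) and Syt1 at -4.88 (SE 0.29). Glial genes gave 8 lower and 2 higher of 11, with repo at -4.50 (SE 0.17), neuroblast genes 10 and 2 of 14, with pros at -5.52 (SE 0.41) and erm at -4.98 (SE 0.29), and ring gland genes 7 lower of 7, with Akh at -5.02 (SE 0.47). Their adjusted p values were 0.363, 0.403, 0.641 and 0.575 with an estimated correlation. The brain-typical transcripts in wing libraries stood at 6.32% in D. simulans, 5.12% in D. virilis and 0.695% to 2.04% in the other 7 lines. Without those 2 lines the neuronal count was 15 lower, the glial count 7 lower and 2 higher, the neuroblast count 10 and 2 and the ring gland count 7 lower.

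Camera called no other list between wing disc and brain. Retinal determination genes gave 5 higher and 5 lower of 11, with toy at -4.72 (SE 0.38) and ey at -3.79 (SE 0.27) against eyg at 2.71 (SE 0.12) and toe at 2.65 (SE 0.15). Photoreceptor genes gave 5 higher and 13 lower of 23, antennal genes 3 and 7 of 10, adult muscle precursors 4 and 3 of 7, phototransduction genes 0 and 3 of 5, posterior Hox genes 0 and 2 of 3, ecdysone response genes 5 and 4 of 17, Notch genes 7 and 4 of 13, EGFR genes 5 and 7 of 15, and hemocyte genes 1 and 1 of 6. Of 12 muscle genes 0 passed, and of 7 fat body genes Rfabg, an apolipoprotein gene, was lower at -1.59 (SE 0.53). Of 2 tested members of the salivary gland list Gp150 was 3.99-fold higher, and of 3 testis genes twe was lower at -0.36 (SE 0.14). For the retinal list the median of -0.17 and the mean of -0.32 stood against a test direction of higher. The EGFR median of -0.05, the ecdysone median of -0.01 and the hemocyte median of -0.31 stood against means of 0.12, 0.28 and 0.14, and with medians set equal the EGFR and ecdysone medians became 0.04 and 0.08.

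Limma called 4622 of 7677 genes, 2164 higher in the wing disc and 2458 higher in the brain, 542 and 1226 of them by at least 2-fold. Under the naming rule, CG4382 was at 4.50 (SE 0.69), Cpr49Ag at 4.44 (SE 0.52), CG17278 at 3.97 (SE 0.17), CG9427 at 3.26 (SE 0.27) and the serpin gene Spn43Aa at 3.03 (SE 0.26), and CG4409, CG9686, CG13928, CG30172, CG14989, CG12239 and Ilp2 spanned -6.27 to -5.72. Camera called 8 of 22 lists. Adjusted over the list alone, counts changed for photoreceptor (15 lower), posterior Hox (1 higher), phototransduction (4 lower) and testis genes (0 lower). Without the 2 lines with brain transcripts 4620 genes were called, 2169 and 2451, of which 4386 were among the 4622. With medians set equal 2567 were higher and 2120 lower, and without the line block 2665 genes were called, all among the 4622.

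**Figure D3:**
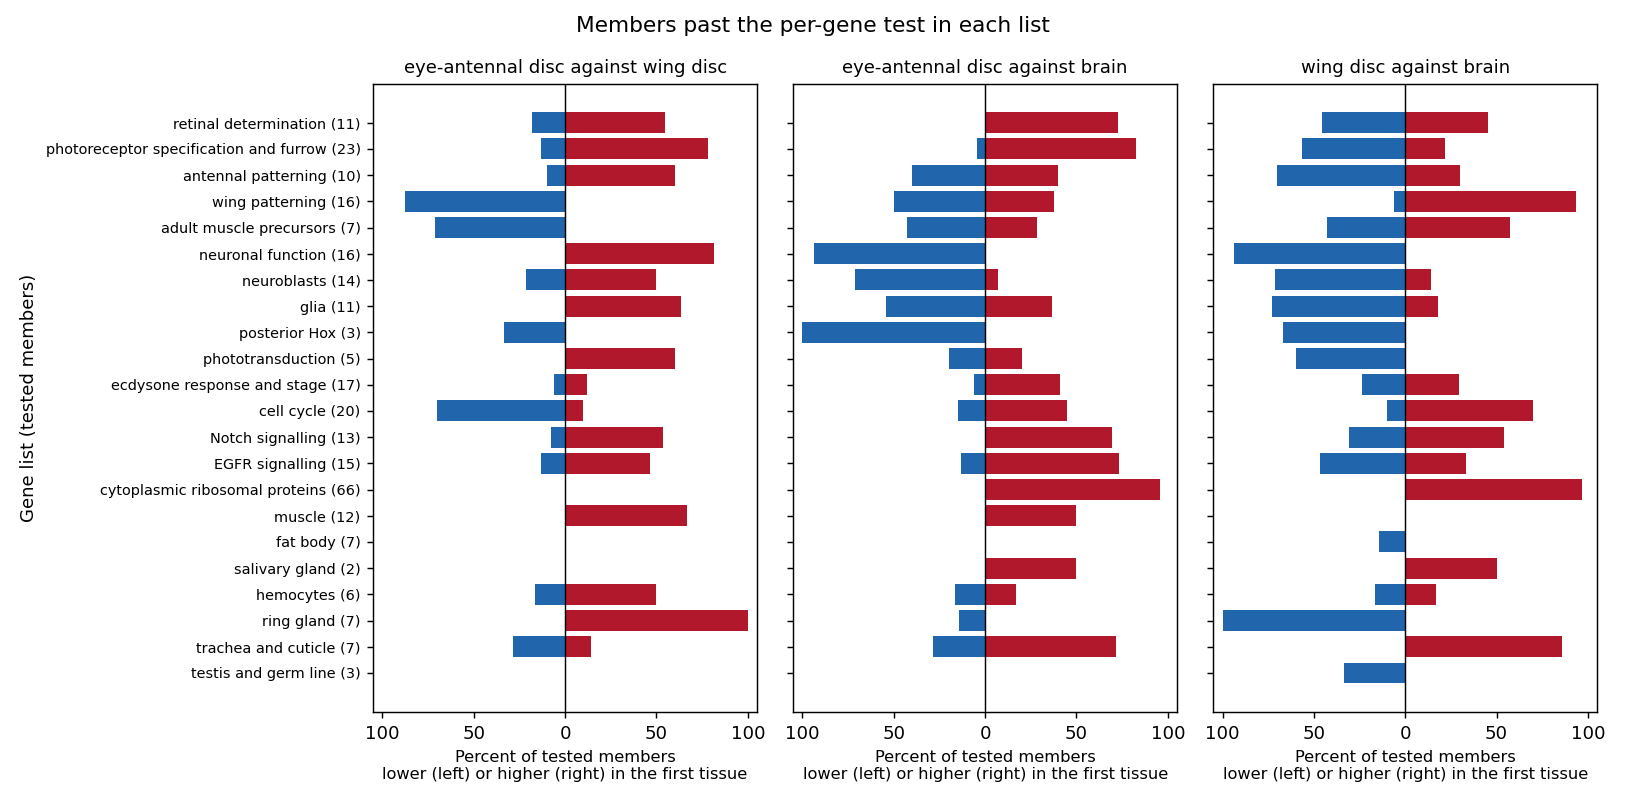
Percent of each list's tested members that passed the per-gene test, higher to the right and lower to the left, in the first tissue named above each panel, with the number of tested members in parentheses. Between eye-antennal and wing disc, 14 of 16 wing patterning genes lie to the left and 18 of 23 photoreceptor genes to the right.

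**Figure D4:**
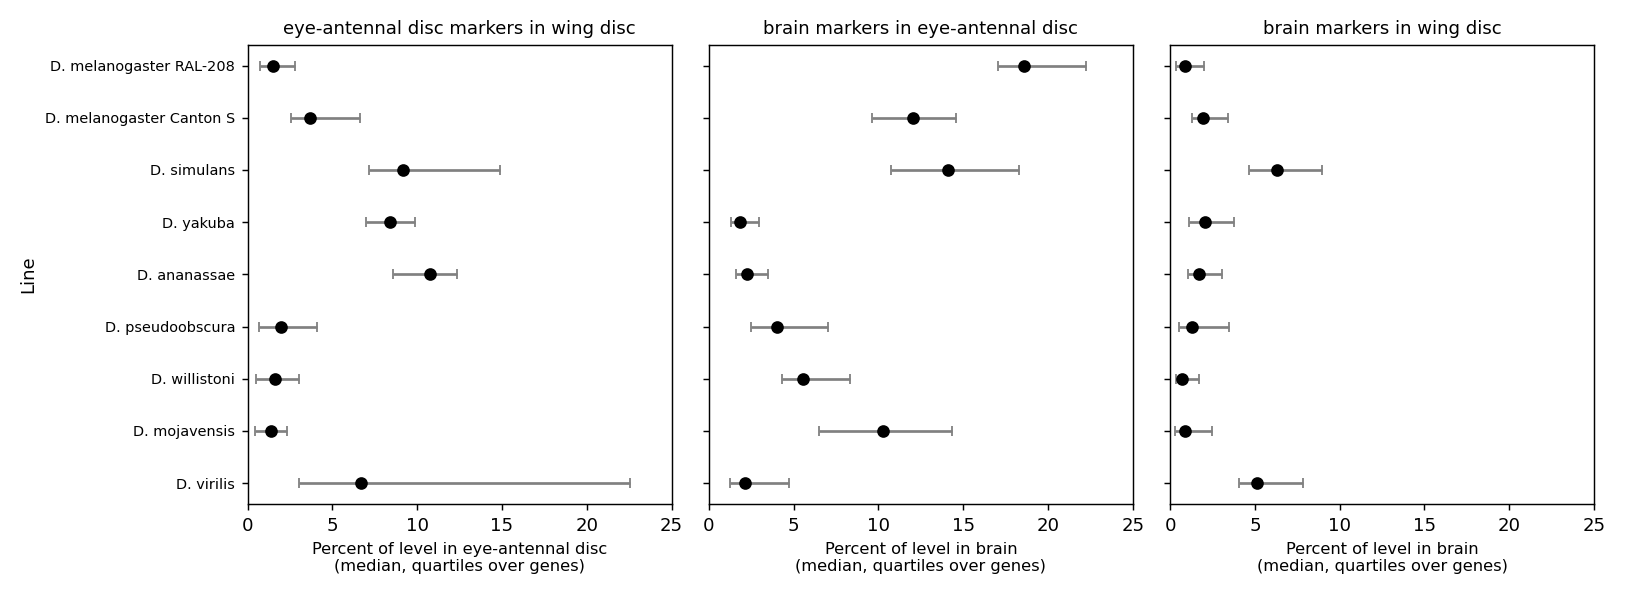
Level of transcripts typical of another tissue in each library, in percent of their level in the source tissue of the same line, as the median over marker genes with quartiles as bars. Eye-antennal markers reach 10.7% in the wing disc library of D. ananassae, and brain markers reach 18.6% in the eye-antennal library of RAL-208.

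Lineage differences asked whether a tissue difference itself differs between the melanogaster subgroup and the other 5 lines. Between eye-antennal disc and brain, CG30440 (FBgn0050440) had a mean log2 difference of 2.23 ± 0.78 (SD, n = 4) in the subgroup and -0.15 ± 0.35 (SD, n = 5) elsewhere, and CG3097 (FBgn0029804) 1.15 ± 0.11 against -0.53 ± 0.17. CG30379 (FBgn0050379) had -2.42 ± 0.35 in the subgroup against 0.03 ± 0.52, and CG8839 (FBgn0033717) -1.41 ± 0.39 against -0.05 ± 0.30. The interaction terms were 2.38 (SE 0.33), 1.68 (SE 0.23), -2.44 (SE 0.40) and -1.36 (SE 0.20). A further gene, CG6055 (FBgn0031918), lay below the rule's level and was chosen after its values were seen, with a term of -3.35 (SE 0.53). In each of these 5 genes the ranges of the lineages did not overlap. They were all that limma called of 7677, with 813 at an unadjusted p under 0.05, against 3 by edgeR and 55 by DESeq2 on recovered counts of 5865 genes. The call of 5 became 0 without the 4 lines with brain transcripts, which leaves D. yakuba alone in the subgroup, 2 without D. simulans, 8 without D. yakuba and 9 without D. ananassae.

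Between eye-antennal disc and wing disc, limma called 0 of 7677 genes for a lineage difference, with 396 at an unadjusted p under 0.05, against 0 by edgeR and 13 by DESeq2. Without D. willistoni 1 gene was called, and without the 4 lines with eye transcripts 7, where the subgroup is D. melanogaster alone.

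The strains RAL-208 and Canton S of D. melanogaster were compared to measure variation within a species. Some genes of the mitochondrial genome, 5 of 10 tested, were called lower in RAL-208: mt:CoII (FBgn0013675), a cytochrome oxidase subunit gene, had 21 reads over the 3 RAL-208 libraries and 12939 over the 3 Canton S libraries, a log2 difference of -9.16 with an SE of 0.47. The cytochrome b gene mt:Cyt-b (FBgn0013678) had 7 reads against 3534 and the ATP synthase gene mt:ATPase6 (FBgn0013672) 8 against 2163, at -8.83 (SE 0.65) and -7.94 (SE 0.58). Drsl2 (FBgn0052279), a gene of the drosomycin family of antimicrobial peptides, had 2 reads against 1283, a log2 ratio of -9.23 with a 95% counting interval of -12.3 to -7.37, and the ion channel gene ppk13 (FBgn0053508) 5 against 1165, at -7.24 (SE 0.51). In RAL-208 the sugar transporter gene sut2 (FBgn0028562) was higher, with 936 reads against 26 and a log2 difference of 6.03 (SE 0.46).

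Further genes higher in RAL-208 were CG4927 at 5.19 (SE 0.34), the UDP-glycosyltransferase gene Ugt86Di at 2.97 (SE 0.17), Ady43A at 2.84 (SE 0.17) and CG5618 at 2.17 (SE 0.09). Of 10 mitochondrial genes tested, 9 were lower in RAL-208 by their fitted value, 5 of them called, and mt:lrRNA, chosen after its values were seen, stood at 1.99 without passing. The mitochondrial genome took 0.0602% of counted reads in RAL-208 and 0.323% in Canton S. Counting intervals cover counting error only. In all, edgeR called 28 of 9476 genes, 12 higher in RAL-208 and 16 in Canton S, each with 1 sign in all 3 tissues, and 1577 had an unadjusted p under 0.05. A p here measures how a difference repeats over tissues of 1 culture, not over cultures. Without the tissue block 0 genes were called. The Canton S level of Drsl2 was 78.0 CPM in the wing disc, 17.0 in the brain and 0.321 in the eye-antennal disc, and its fitted log2 difference of -8.14 became -7.21 without the Canton S wing library and -10.91 without the Canton S brain library. With each of the 6 libraries left out in turn, fitted values spanned -10.24 to -8.39 for mt:CoII, -11.15 to -7.57 for mt:Cyt-b, -9.40 to -6.77 for mt:ATPase6, -8.19 to -6.86 for ppk13 and 5.71 to 7.18 for sut2. The count of genes also rested on single libraries: it was 0 without either brain library, 1 without either eye-antennal library, and 243 and 283 without the wing disc library of RAL-208 or Canton S. DESeq2 called 504 and a run without the filter 43.

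The lists were also tested between the strains, an addition made after the data were seen. Camera called 5 lists, none of them with an estimated correlation, where the adjusted p of each was 0.820. Higher in RAL-208 were wing patterning at a median of 0.33, neuroblasts at 0.32 and muscle at 1.18, and lower were ribosomal proteins at -0.19 and salivary gland at -0.89, a list with the glue gene Sgs7. Adjusted over the list alone, 2 wing patterning, 3 neuroblast and 1 testis genes were higher and 5 salivary gland genes lower. Adjusted over all genes, Sgs7, chosen after its values were seen, was the only member of any of the 22 lists that passed. Neuronal genes had a median of 0.36 in the same direction as neuroblasts, without a call. Brain-typical transcripts stood at 18.6% of their brain level in the RAL-208 eye-antennal library against 12.0% in that of Canton S. In the wing libraries the order was the other way, at 0.868% in RAL-208 against 1.92% in Canton S. Whether such transcripts bear on these medians was not tested.

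How far expression had diverged between species was measured in each tissue, since the series concerns the evolution of expression in eye-antennal discs. In the eye-antennal disc, similarity to D. melanogaster was lower for D. simulans than between the strains and lowest for D. virilis. The Spearman correlation across genes was 0.977 between the strains, 0.889 with D. simulans, 0.846 with D. yakuba and 0.837 with D. ananassae. It was 0.806 with D. pseudoobscura, 0.828 with D. willistoni, 0.815 with D. mojavensis and 0.773 with D. virilis. Beyond D. ananassae it thus did not fall steadily with split time. The log2 rate ratio of the eye-antennal disc over the brain was 0.30 on average over 7 contrasts (SD 0.28), higher in 6 of 7, with an exact permutation p = 0.0469 and an adjusted p of 0.109 over 3 pairs. Eye-antennal disc over wing disc gave 0.17 (exact p = 0.109, higher in 6 of 7) and wing disc over brain 0.14 (exact p = 0.0781, higher in 5 of 7), so no pair passed after adjustment. The smallest p that the sign flips can give is 0.0156. The shares of brain and eye transcripts in disc libraries differed between lines, as given above, and may add to the rates of the discs. The rates were recomputed without 1 species at a time, but not without all of those lines. With a pseudocount of 0.1, eye-antennal disc over brain and wing disc over brain passed at 0.31 and 0.29, each with an adjusted exact p of 0.0469. Eye-antennal disc over wing disc then fell to 0.02, higher in 2 of 7 contrasts (exact permutation p = 0.922). With Canton S alone the 2 ratios over brain passed at 0.32 and 0.18. Without D. simulans eye-antennal disc over wing disc passed at 0.19 and over brain at 0.36.

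The fastest contrast in each tissue was that of D. melanogaster and D. simulans, at a mean squared log2 difference of 0.109 per My (megayear) of summed branch length in the eye-antennal disc, 0.123 in the wing disc and 0.126 in the brain, or 0.0648, 0.0789 and 0.0807 without doubtful entries. This contrast spans the shortest branches, where noise of single libraries weighs most. Yet the root mean square log2 difference between the strains was 0.50, 0.74 and 0.52 in these tissues. Between D. melanogaster and D. simulans it was 1.05, 1.11 and 1.12, so noise of the size of the strain difference alone falls short of it. Differences in orthologs and annotation between species also enter this contrast, and their share was not tested. Noise at the tips, taken from the strain difference, made up 16.6% of the mean square over all contrasts in the eye-antennal disc. Its share was 37.0% in the wing disc and 18.7% in the brain. The 5 genes with the highest rates in the eye-antennal disc were near 0 in 1 species. The 14-3-3 adaptor gene 14-3-3zeta (FBgn0004907) was at 0 in D. simulans and at 559 to 1350 in the other lines, and CG43780, CG41503, CG30382 and the proteasome gene Prosalpha1 were at 0 to 0.342 in D. melanogaster and at 139 to 611 in the other species. CG30382 and Prosalpha1 hold identical values in every library outside D. melanogaster.

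**Figure D5:**
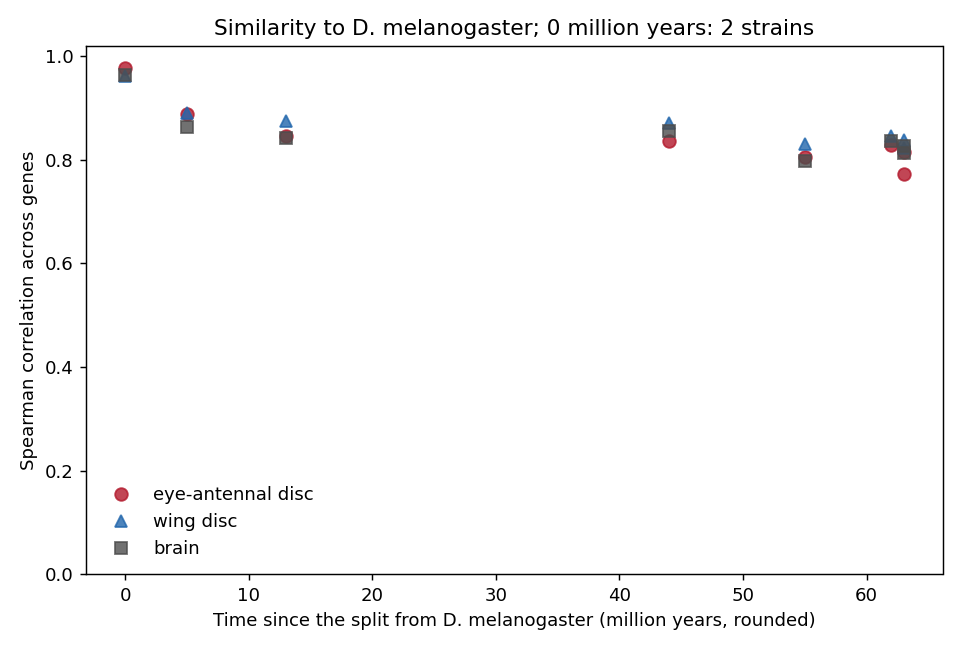
Spearman correlation across genes between D. melanogaster and each other species against rounded split time in My, by tissue, with the 2 D. melanogaster strains at 0. In the eye-antennal disc it is 0.977 between the strains, 0.889 for D. simulans and 0.773 for D. virilis. For D. mojavensis, at the same split time as D. virilis, it is 0.815.

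An Ornstein-Uhlenbeck model, in which expression is drawn back to an optimum, was set against Brownian drift, as the series names these methods. In the eye-antennal disc 1281 of 7677 genes favoured the Ornstein-Uhlenbeck model, and 2784 had an unadjusted p under 0.05. The 5 genes with the strongest ratio were CG1407 (FBgn0033474), the laminin gene LanB1 (FBgn0261800), the tetraspanin gene Tsp39D (FBgn0032943), the myosin V gene didum (FBgn0261397) and the cytochrome oxidase gene CoVIIc (FBgn0040773), with SDs between species of 0.35, 0.27, 0.50, 0.64 and 0.58 on the log2 scale. In each of these 5 genes, both D. melanogaster strains stood at 1 end of the lines and D. simulans at the other. CG1407, for example, was at 22.5 and 18.1 in the strains, 48.4 in D. simulans and 30.9 to 38.8 in the other lines. The fitted return rate of these 5 genes was 30, the top of the range searched. These 5 genes are among 258 that no simulation under Brownian drift matched, and their order among these 258 is by the likelihood ratio. Of the lists, retinal determination had 3 of 11 such genes, photoreceptor specification 5 of 23 and wing patterning 0 of 16. In the wing disc 2157 genes and in the brain 2477 favoured this model, and 932 of the eye-antennal genes were shared with the wing disc and 892 with the brain, against 360 and 413 if the tissues were independent. They share lines, orthologs and annotation, so a larger overlap does not by itself show a shared constraint, and differences between tissues in these counts were not tested. For 1009 of the 1281 genes the return rate lay at the top of the range searched, where noise without phylogenetic structure has the same form. The 5 genes with the highest rates in the eye-antennal disc, each near 0 in 1 species, are also among the 258 and the 1281. Without doubtful entries 1055 of 7491 genes favoured the model. With Grafen branch lengths 823 of 7677 did, of which 358 were among the 1281. The count was 0 without D. melanogaster, 0 without D. simulans, 785 without D. ananassae, 770 without D. pseudoobscura, 680 without D. willistoni and 682 without D. mojavensis, and 513 against a Brownian null with noise at the tips of the tree. Against that null the counts were 463 in the wing disc and 1094 in the brain. The null used 1 noise level and 1 rate per tissue, each averaged over genes. Its counts are therefore not corrected for the noise of each gene.

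The D. simulans line carries an allele of white, whose gene w encodes a pigment transporter of the eye. Its signal was 13.4 in the eye-antennal disc, from 71 reads, 2.62 in the wing disc, from 17 reads, and 1.35 in the brain, from 13 reads. In the eye-antennal discs of the other lines it ranged from 1.14 in D. willistoni through 31.6 in D. yakuba to its highest value in D. pseudoobscura, from 994 reads.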

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

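The tests over other splits of the lines in this part were chosen after the results were seen; the search for lines standing apart and the lineage tests were planned.

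The search covered 132 groups of 9 lines, most of them the differences of 1 list or 1 named gene between a pair of tissues. The rest were read totals per tissue and shares of other-tissue transcripts. The groups share lines and genes, so they are not independent. In each group, the gap of the highest or lowest line to its neighbour was compared with the range of the group. It was large in 10 groups, or 7.58%, where chance gives about 1 in 20, which is 6.60 groups. D. virilis stood apart in 4 of them, D. willistoni in 3, and RAL-208, D. mojavensis and D. pseudoobscura in 1 each.

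Between eye-antennal and wing disc, the mean log2 difference of retinal determination genes was highest in D. willistoni, at 2.27 against 1.68 for the next line. Glial genes were lowest in D. virilis, at 0.13, with every other line above 1. Ecdysone response genes were highest in D. mojavensis, at 0.78 against 0.37. Ribosomal protein genes were highest in D. virilis, at 0.37 against -0.0045. Ring gland genes were lowest in D. willistoni, at 0.21 against 1.87, and its wing library held Akh at 91.1 and phm at 32.6. Trachea and cuticle genes were lowest in D. pseudoobscura, at -1.21 against -0.75.

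Between eye-antennal disc and brain, CG13064 was highest in D. virilis, at 6.02 against 4.12. CG4374 was lowest in RAL-208, at 1.79 against 2.75. ImpE2 was highest in D. virilis, at 4.69 against 2.91. Between wing disc and brain, CG4382 was lowest in D. willistoni, at 0.12 against 3.50.

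The difference between eye-antennal disc and brain differed between the melanogaster subgroup and the other 5 lines in 5 genes, by an interaction term of 2.38 for CG30440, 1.68 for CG3097, -1.36 for CG8839, -2.44 for CG30379 and -3.35 for CG6055. Of 100 splits of the 9 lines into 4 and 5, 1 gave as many genes, the real one, and the highest other gave 4. The lines share ancestry, and RAL-208 and Canton S are of 1 species, so the lines are not exchangeable. These splits thus argue only weakly against an arbitrary split of the lines for that count. For eye-antennal against wing disc, where 0 genes were called, all 100 splits reach that count by construction, so they decide nothing about it. The highest other split gave 26, with D. yakuba, D. ananassae, D. pseudoobscura and D. virilis set apart, and what these lines share was not tested.

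Genes without a value in at least 1 species were not used in any comparison, and 1930 of these 5607 genes had a signal of at least 10 in a library.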

How the results depend on the processing

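The alternatives on recovered counts, on genes with a mean of at least 10, without doubtful entries and without lines with other-tissue transcripts were chosen after seeing the data, as were those on genes matched in all lines and medians set equal for divergence and the Ornstein-Uhlenbeck test. Counts of genes between tissues stayed within 1.5 times under 20 alternatives each, from 1123 to 1988 for eye-antennal against wing disc, 3188 to 4080 for eye-antennal disc against brain and 3704 to 4829 for wing disc against brain. No named gene reversed: values between eye-antennal and wing disc kept direction and side of the threshold in 1483 cases and lost the threshold in 84, over 20 genes; for eye-antennal disc and brain these were 1703 and 18, for wing disc and brain 1765 and 25, and for the strains 52 and 48. Depth limits the genes near 0, such as the 2 reads of Drsl2.

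Without the replicate block, which is line for tissues and tissue for strains, the tissue counts were 709, 2122 and 2665, and the strain count 0; these fits leave the spread between lines, or between tissues for the strains, in the error. Without the lines with brain transcripts in a disc, eye-antennal against wing disc gave 753, with 4 lines left. The lineage difference between eye-antennal and wing disc, 0 in the report, was 8 for Sophophora against D. mojavensis and D. virilis, 5 without filter, 13 with DESeq2 and 7 without the lines with eye transcripts (D. melanogaster against 3 species), and 0 to 1 over the lines left out. That between eye-antennal disc and brain, 5 in the report, was 45 for Sophophora, 3 with edgeR and with limma on 5865 genes, 55 with DESeq2 and 0 without the lines with brain transcripts, and 2 to 9 over the lines left out. Lists called with an estimated correlation were 1, 0 and 0; fry called 17 for eye-antennal disc and brain and 19 for wing disc and brain, and tests another hypothesis. The strain count was 43 without filter, 504 with DESeq2, and 0 to 283 over the libraries left out.

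Rate ratios passed the threshold with a pseudocount of 0.1 (eye-antennal disc over brain 0.31, wing disc over brain 0.29), with Canton S alone (0.32 and 0.18), and without D. simulans (eye-antennal disc over wing disc 0.19, over brain 0.36). The log2 ratios ranged from 0.02 to 0.34 for eye-antennal disc over wing disc, 0.25 to 0.42 for eye-antennal disc over brain and 0.07 to 0.29 for wing disc over brain. The value of 0.02 came with a pseudocount of 0.1. Without 1 species eye-antennal disc over wing disc gave 0.11 (D. ananassae) to 0.20 (D. pseudoobscura). Ornstein-Uhlenbeck counts were 823 with Grafen branch lengths, of which 358 were among the 1281, 513 with tip noise, and 0 to 991 over the species left out. Fits without 1 species have 1 tip fewer. Apart from these, the cause was not tested.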

Other observations

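All tests of explanations in this part were chosen after the results were seen, and so were the counts over other splits, and the test of the rates of gene lists.

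Some groups of genes had higher rates than random lists of the same size and expression level. Fat body genes did so in the eye-antennal disc, at a median rate of 0.390 against 0.00663 for random lists (adjusted p = 0.0038 over random lists), with the storage protein gene Lsp2, chosen after its values were seen, the fastest, and also in the wing disc (adjusted p = 0.049 over random lists) and the brain (adjusted p = 0.0063 over random lists). Muscle genes did so in the wing disc, at 0.0993 against 0.0193 (adjusted p = 0.011 over random lists), and in the brain, at 0.184 against 0.0107 (adjusted p = 0.0038 over random lists). Ribosomal protein genes in the brain had a median of 0.0139 against 0.00646 (adjusted p = 0.0057 over random lists). Retinal determination genes, at 0.00618 against 0.00668 in the eye-antennal disc, and wing patterning genes, at 0.00394 against 0.00595 in the wing disc, did not differ from random lists by this test (adjusted p = 0.94 and 0.54). Tissue carried over in single libraries would also raise the rates of fat body and muscle genes; this was not tested and stays open.

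The posterior Hox gene abd-A stood at 3.19, 3.09 and 3.42 in the eye-antennal libraries of RAL-208, Canton S and D. mojavensis, at 9.82, 11.5 and 11.5 in their brains, and at 0 to 0.558 in the eye-antennal libraries of the other 6 lines.

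The first pattern weighed is that eye transcripts stood at 8.37% to 10.7% of their eye-antennal level in the wing disc libraries of D. simulans, D. yakuba and D. ananassae. RNA from eye-antennal discs would bring all such transcripts at 1 share, and at least 86.7% of the marker genes lay within 2-fold of the median share in each of the 3 libraries, which is consistent with it. These 3 libraries were chosen after their shares were seen; the D. virilis wing library, at 6.70%, had 40% of markers within 2-fold and quartiles of 3.00% and 22.6%, which RNA of that 1 kind alone would not give. RNA from the brain is argued against in D. yakuba and D. ananassae, where brain markers stood at no more than 2.04%, and cannot be told apart in D. simulans, where they stood at 6.32% and both kinds may be present. A change on 1 branch of the tree is argued against, because the D. melanogaster strains, which branch within these species, had at most 3.68%, while expression in the wing disc that arose separately in these species was not tested and stays open.

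The second pattern is that 9 of 10 mitochondrial genes were lower in RAL-208 by their fitted value, 5 of them called, with a median of -3.15 over the 10. A drop of the same size in all mitochondrial genes is argued against by 2 called genes. The gene mt:CoI, chosen after its values were seen, stood at -2.19 (SE 0.17) and mt:CoII at -9.16 (SE 0.47). In the other direction, mt:lrRNA stood at 1.99 without passing, and its interval above 0 covers counting error only. Less mitochondrial RNA by unequal amounts stays open, since the mitochondrial genome took 0.0602% of counted reads in RAL-208 and 0.323% in Canton S. Fewer reads in RAL-208 are argued against, since its eye-antennal library had 0.980 times and its brain library 1.54 times the reads of Canton S, and the median log2 ratio of the 10 genes was -2.73 and -3.42 there, with upper quartiles of -1.53 and -1.57. A strain variant against the reference genome, which may keep reads from aligning, cannot be told apart from a true difference, since the 21 reads of mt:CoII left in RAL-208 give a number and no sequence.

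The third pattern is that 91 of 7677 genes were near 0 in D. melanogaster alone, against 2 to 11 in each other species. Reads in exons shared by different genes are not assigned to either by common counting rules, and 67.8% of the 87 of these genes with an annotation had at least 90% of exon bases inside another gene, against 1.74% of other tested genes; this overlap is from an Ensembl reference annotation that need not be the one used for counting. An ortholog assigned to several D. melanogaster genes is a further candidate source, since 20.9% of the 91 repeated the values of another gene in the 7 other species, against 0.778% of other genes. Library depth is argued against, since D. mojavensis had 5 such genes. A loss of expression in D. melanogaster was not tested and stays open for the rest.

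The counts of called genes between tissues were set against 100 splits, the real one included, that swap the tissues within lines. The real split gave 1633 genes for eye-antennal against wing disc and the highest other 686, with D. pseudoobscura and D. virilis swapped; 4039 against 10 for eye-antennal disc and brain; and 4622 against 400 for wing disc and brain, again with D. pseudoobscura and D. virilis swapped. In each, 1 split of 100 reached the real count, which argues against an arbitrary split of the labels as the source. Called lists were 14, 10 and 8, reached by 2, 2 and 4 of the 100 splits, whose highest others were also 14, 10 and 8 and whose medians were 5, 5 and 4, so the share stays under 0.05. Splits that swap some lines keep part of the tissue difference, so these medians are not counts without any. For the strains, 10 splits of the 6 libraries cannot give a share under 0.05; the real split gave 28 genes, and the highest other 0.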
